A study of Homo sapiens with 6 samples.

How the data were processed

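Bulk RNA sequencing of HK-2 cells, an immortalised line of human proximal tubule epithelium, was analysed from 1 deposited table with 16274 gene rows. The labels give 6 samples, 3 of wild-type (WT) genotype and 3 of TAX1BP1-KO genotype, and call the samples of a group biological replicates. They do not say how the knockout was made or whether the replicates came from separate clones, so the p-values measure the spread between these 3 cultures of each group. The treatment label reads normal in every sample, although the column names of the table also carry the letters DMSO. Total RNA was extracted with RNAiso Plus, per the labels' protocols. The protocols describe no library kit and no strand setting, so reads of overlapping and antisense genes cannot be told apart.

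The authors deposited estimated counts of reads per gene (expected counts) without normalization. The file headers call them read counts, and they are taken as estimated because 11.7% to 13.1% of the values in a library were not whole at a tolerance of 0.005. The authors also deposited TPM (transcripts per 1000000 transcripts) for the same rows, per the file headers, and each TPM column summed to 1000000. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1 and Cuffdiff 2.2.1 and the build GRCh37. Which tool made the counts, and on which annotation, is not given in the sources used here. Non-whole counts can arise where a counter divides reads between overlapping or near-identical genes, so genes with close copies are uncertain. The design chosen beforehand assumed whole counts, and the estimated counts were therefore rounded, which moved the total of a library by at most 15 counts.

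Gene symbols were taken from the table. Its Entrez identifiers were matched to the RefSeq gene table of assembly GRCh38.p14, where 16220 of 16274 identifiers were found and 54 were not. That assembly differs from the build in the notes, so it served only for the class of each gene and for which genes neighbour each other, and no coordinates are given. No row belonged to the mitochondrial genome, so the list of mitochondrially encoded messenger RNAs had no members.

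Library totals ran from 15615765 to 17124685 counts. Genes with too few counts were removed with filterByExpr, which left 12857 genes. Libraries were scaled by TMM and compared with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Fold changes are log2 values of the libraries labelled KO over WT, with standard errors (SE) derived from the F statistic. Expression levels are TMM-scaled counts per 1000000 counts (CPM), as mean ± SD over 3 libraries. The common biological coefficient of variation was 6.76%. For a gene with 0 counts in all libraries of a group, the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio is given with its 95% counting interval, which covers counting error only.

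Before the data were examined, 39 gene lists and the rule for naming genes were fixed. The rule takes TAX1BP1, PRKAA1, PRKAA2 and ULK1, then the 10 largest rises and 10 largest falls among changed genes with at least 5 CPM in the higher group and no overlap between groups. It further takes up to 4 changed members of each list by smallest adjusted p and the 5 most abundant genes changed at least 2-fold. Genes named outside this rule are marked as chosen after their values were seen. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01), adjusted over the lists. Camera compares the genes of a list with all other genes, and it was repeated with an estimated correlation between genes, on ranks, and with fry, which tests whether the genes of a list move one way without comparing them with other genes.

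The TPM values were tested with limma (trend) on log2(TPM + 1) for the 12194 genes with a mean of at least 1 TPM. Fold changes on this scale are smaller for genes of low expression. Replicates were compared by correlation of log2 CPM and by the chi-square of their counts. Runs of neighbouring genes were searched, after the data had been seen, with a running median over 25 genes of at least 4 CPM along each chromosome. A run was a stretch of at least 25 genes whose running median lay at least 0.3 from 0 on the log2 scale. The first and last 12 of these genes on each chromosome had no running median. They were counted as outside a run, whatever their neighbours did. The search was repeated on 200 shuffled gene orders.

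Alternatives fixed beforehand were other size factors, total counts only, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter, a replicate block, the TPM values, each library left out in turn, other thresholds, and other pseudocounts and filters for TPM. A test without the genes of the shifted runs, and another with the running median of neighbouring genes as an offset, were added after seeing the data. The offset was estimated from the same libraries and entered as if known exactly. All p-values with the neighbour offset therefore leave out its error. The steps were tested on simulated data. For edgeR, counts were drawn from the means of these libraries and 200 genes picked at random were changed. On 12805 genes edgeR recovered 82.1% of changes of 1.5-fold, 94.0% of changes of 2-fold and 98.5% of changes of 4-fold. False calls numbered 9 (4.69% of its calls). In the real data 49.3% of genes were called and neighbouring genes shifted together, so these rates need not hold there. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.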

Results

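The transcriptomes of WT HK-2 cells and of HK-2 cells labelled TAX1BP1-KO were compared, with 3 libraries in each group. TAX1BP1 is a ubiquitin-binding autophagy receptor and a partner of the NF-kB regulator A20, and the series title asks about its part in starting autophagic flow and in the AMPK-ULK1 pathway. The WT libraries held 17124685, 16264523 and 16889089 counts and the libraries labelled KO held 15615765, 16159434 and 16542829 counts. Replicates correlated at 0.99 to 0.995 within WT and at 0.994 to 0.996 within the group labelled KO (Pearson, log2 CPM across genes), against 0.948 to 0.953 between groups. The chi-square of counts over that of counting error alone was 1.36 to 2.13 within the group labelled KO, 2.39 between WT replicates 1 and 3, 4.73 and 6.71 between WT replicate 2 and the other WT libraries, and 14.7 to 19.6 between groups. The first principal component held 84.3% of the variance and separated the groups.

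TAX1BP1 messenger RNA was at the WT level in the libraries labelled KO. TAX1BP1 (Entrez gene 8887) measured 181, 168 and 193 CPM in the WT libraries and 182, 178 and 169 CPM in the libraries labelled KO, with 2716 to 3238 counts per library. The KO over WT ratio was 0.97 (95% interval 0.881 to 1.08, n = 3 per group), and edgeR's quasi-likelihood test gave an adjusted p of 0.67 after Benjamini-Hochberg adjustment. A total per gene does not show reads across an edited site. The knockout is therefore named only as the label gives it, and every direction below is that of the libraries labelled KO against WT.

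Of the AMPK catalytic subunits, PRKAA2 fell and PRKAA1 did not change detectably, and no change was detected in ULK1, the kinase that starts autophagosome formation. PRKAA2 (Entrez gene 5563) went from 52.2 ± 10.2 CPM in WT to 31.6 ± 3.15 CPM (SD, n = 3), a log2 fold change of -0.73 ± 0.13 SE, and was lower in all 3 libraries labelled KO than in any WT library. PRKAA1 (Entrez gene 5562) measured 104.5 ± 12.9 CPM in WT and 109.1 ± 7.68 CPM in the libraries labelled KO, a ratio of 1.04 (95% interval 0.908 to 1.20). ULK1 (Entrez gene 8408) measured 42.4 ± 1.78 and 42.1 ± 1.33 CPM, a ratio of 0.991 (95% interval 0.90 to 1.09). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.0011 for PRKAA2, 0.61 for PRKAA1 and 0.88 for ULK1.

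**Figure D1:**
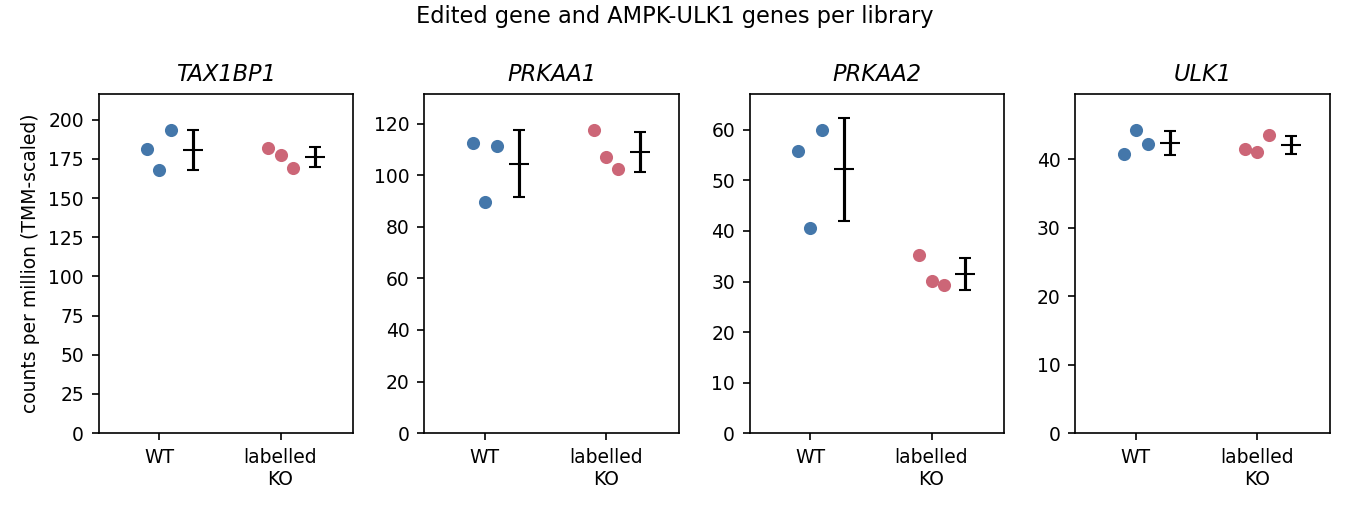
TMM-scaled CPM (vertical axes, from 0) of TAX1BP1, PRKAA1, PRKAA2 and ULK1 in each library of the WT group and of the group labelled KO; points are libraries and bars are mean ± SD (n = 3). TAX1BP1 lay between 168 and 193 CPM in WT and between 169 and 182 CPM in the libraries labelled KO, and of these genes only PRKAA2 differed beyond the spread between libraries.

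The list of AMPK subunits and upstream regulators moved in both directions. Of its 19 tested members, 4 rose, 6 fell and 9 did not pass. SESN3, a stress-induced sestrin, rose from 1.54 ± 0.325 to 5.62 ± 0.221 CPM, and the regulatory subunit PRKAB1 rose by 0.46 ± 0.08 on the log2 scale. The folliculin partner FNIP2 (log2 fold change -0.69 ± 0.07) and the sestrin SESN2 (-0.51 ± 0.06) fell, and both lay in runs of neighbouring genes that were lower together. In the list of autophagy initiation and nucleation, 3 of 21 rose, 5 fell and 13 did not pass. ATG13, a partner of ULK1, rose by 0.31 ± 0.05, while the lipid scramblase ATG9A (-0.43 ± 0.07), the lipid kinase PIK3C3 (-0.27 ± 0.06) and WDR45 (-0.49 ± 0.09), which lay in a run, fell. Over both lists 18 of 40 genes changed (7 higher, 11 lower), and 18 also passed when adjusted over the list alone, beside 49.3% of all tested genes. No difference of either list from other genes was detected (camera, adjusted p = 0.98 for both).

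Later steps of autophagy also held members of both directions. Among ATG8 proteins and their conjugation enzymes, 3 of 16 rose and 3 fell, with GABARAPL1 (0.26 ± 0.07) and ATG16L1 (0.29 ± 0.06) higher and MAP1LC3B (-0.30 ± 0.07) and ATG4A (-0.71 ± 0.11, in a run) lower. Of 19 selective autophagy receptors, 4 rose and 3 fell. NCOA4, the receptor for ferritin, went from 407 ± 8.32 to 504 ± 2.27 CPM, FKBP8 rose by 0.28 ± 0.06, and the mitophagy genes PINK1 (-0.49 ± 0.07) and FUNDC1 (-0.51 ± 0.10, in a run) fell. For fusion of autophagosomes with lysosomes, 6 of 18 rose and 2 fell, with STX17 (0.26 ± 0.07) and VPS39 (0.27 ± 0.06) higher and LAMP2 and PLEKHM1 (-0.25 ± 0.06) lower, and 6 passed when adjusted over the list alone. With the median of neighbouring genes as an offset, an alternative added after seeing the data, the calls of ATG13, GABARAPL1, FKBP8, ATG4A, WDR45 and LAMP2 were lost, FUNDC1 (0.019) turned sign without passing, and SESN2 turned to 0.34 and passed as higher (adjusted p = 0.0012, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Here and below, p-values with the neighbour offset leave out the error of the offset itself. In TPM the calls of PIK3C3 and PLEKHM1 were lost.

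Of 49 lysosomal genes, 12 rose, 16 fell and 21 did not pass. The protease cathepsin L, CTSL, fell from 68.9 ± 8.46 to 18.3 ± 2.31 CPM, and the transcription factor MITF fell from 64.9 ± 3.08 to 36.0 ± 1.10 CPM. LAMP2 (328 ± 19.7 to 190.5 ± 4.16 CPM) and PPT1 (316 ± 8.45 to 173 ± 4.15 CPM) fell as well and lay in runs, and PPT1 turned to 0.035 on the log2 scale with the neighbour offset. In the vacuolar ATPase, which acidifies lysosomes, none of 19 genes rose and 4 fell: ATP6V0A1 (-0.53 ± 0.06), ATP6V0A4 (-1.05 ± 0.30, at 1.28 ± 0.274 CPM in WT), and ATP6V0B (-1.16 ± 0.08) and ATP6AP2 (-0.50 ± 0.07), the last pair in runs. The call of ATP6V0A4 was lost without WT replicate 1, without replicate 2 of the group labelled KO, and in DESeq2, and ATP6AP2 turned to 0.011 with the neighbour offset. Of 29 genes of the mTOR complexes and their regulators, 5 rose and 10 fell. RRAGC (-1.03 ± 0.06) and MTOR (-0.57 ± 0.06) lay in runs, TBC1D7 (-0.92 ± 0.10) did not, PRR5 rose by 0.65 ± 0.07, and MTOR turned to 0.37 with the neighbour offset, where it passed as higher (adjusted p = 0.00054, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In each of these 3 lists as many genes passed when adjusted over the list alone, and no difference from other genes was detected (camera, adjusted p = 0.26, 0.56 and 0.57).

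Across the transcriptome, 6343 of 12857 tested genes (49.3%) changed, 3027 higher and 3316 lower in the libraries labelled KO, by edgeR's quasi-likelihood test. Without WT replicate 2, which stood apart from the other WT libraries, 7237 genes changed (3432 higher, 3805 lower). At least 2-fold changes were seen in 1139 genes, 562 higher and 577 lower, and the groups did not overlap for 57.8% of genes, against 10% by chance. The deposited TPM values gave 5490 changed genes of 12194 in limma, 3256 higher and 2234 lower, so that 59.3% of the calls were higher against 47.7% by counts, and at least 2-fold changes in 571 genes. The median of all genes was shifted by 0.07 on the log2 scale in TPM, 4840 genes were called in both units, and all 4840 went the same way.

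Several genes expressed in WT were nearly or wholly silent in the libraries labelled KO. PBDC1 (16.6 ± 1.33 CPM in WT), the zinc finger genes ZNF43 (11.01 ± 3.81 CPM) and ZNF711 (5.55 ± 0.557 CPM) and the forkhead factor FOXC2 (7.48 ± 1.06 CPM) had 0 counts in all 3 libraries labelled KO. They were at least 269-fold, 179-fold, 90.3-fold and 122-fold lower against 3 counts over the group. FNDC10 and ZNF736 had 1 count, with WT over KO ratios of 410 (95% counting interval 73.2 to 16232) and 403 (72.0 to 15961). In TPM, ZNF736 had a mean of 1.96 in WT and 0.09 in the libraries labelled KO, a much smaller fold than by counts. The BMP antagonist GREM1 fell from 63.7 ± 2.31 to 0.227 ± 0.0778 CPM, RBM23 from 28.2 ± 2.04 to 0.368 ± 0.154 CPM, KBTBD7 from 15.3 ± 1.51 to 0.0812 ± 0.0914 CPM, and the adenylate cyclase ADCY1 from 9.09 ± 0.561 to 0.105 ± 0.132 CPM. PBDC1, FNDC10 and ZNF711 lay in runs of lower genes. Zinc finger genes have close relatives, so the counts of ZNF43, ZNF711 and ZNF736 are uncertain where reads were divided.

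The largest rises included TLR4, the receptor for lipopolysaccharide, with 2 counts in WT and 262 in the libraries labelled KO, a ratio of 134 (95% counting interval 36.7 to 1111). The transcription factors ATOH8 (0.201 ± 0.0397 to 14.4 ± 0.243 CPM) and NFIA (0.102 ± 0.094 to 5.28 ± 0.207 CPM) rose, as did PLXDC2 (0.683 ± 0.365 to 32.8 ± 0.190 CPM), AMOTL1 (0.861 ± 0.344 to 39.1 ± 0.878 CPM) and STXBP6 (0.283 ± 0.218 to 9.64 ± 0.602 CPM). NEBL rose by 4.40 ± 0.12 on the log2 scale, and the adhesion genes CNTN5, NLGN1 and PCDHGB7 rose by 5.17 ± 0.36, 4.31 ± 0.14 and 4.39 ± 0.23. PCDHGB7 belongs to a cluster of genes that share exons, so its count is uncertain. Of the abundant genes, MYSM1, a histone H2A deubiquitinase, rose from 80.4 ± 9.92 to 1507 ± 85.8 CPM. The complement component C3 rose from 1173 ± 41.3 to 2500 ± 70.6 CPM, IGFN1 from 845 ± 136 to 1715 ± 81.0 CPM and PLCB4 from 498 ± 55.9 to 1179 ± 35.3 CPM, and HMGA1, in a run, fell from 1174 ± 80.2 to 555 ± 16.7 CPM.

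Genes of glycolysis were lower together. Of 21 tested members 17 fell, 1 rose and 3 did not pass, with a median log2 fold change of -0.52, and 18 changed when adjusted over the list alone. The glucose transporter SLC2A1 fell from 262 ± 20.8 to 86.7 ± 3.95 CPM, the lactate transporter SLC16A1 from 419 ± 40.1 to 200.3 ± 8.29 CPM, PGK1 from 479 ± 42.9 to 237.5 ± 1.58 CPM and the hexokinase HK1 from 108.5 ± 4.89 to 55.2 ± 2.63 CPM. The member that rose was PFKL (0.55 ± 0.06), named after its value was seen. SLC2A1, PGK1 and SLC16A1 lay in runs, and outside the runs 12 of 16 members fell, with a median of -0.38. Hypoxia targets fell too, with 13 of 20 lower, 1 higher and a median of -0.36, and 16 changed when adjusted over the list alone. ANGPTL4 went from 13 ± 0.803 to 3.78 ± 0.464 CPM, SLC2A3 from 20.4 ± 0.790 to 7.67 ± 0.591 CPM and the prolyl hydroxylase P4HA1 from 69.8 ± 2.29 to 40.9 ± 0.899 CPM, while KDM3A, named after its value was seen, rose by 0.46 ± 0.06. Camera gave an adjusted p of 2.6e-05 for glycolysis and 0.0022 for hypoxia targets, and an adjusted p of 0.69 for both with an estimated correlation.

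Genes of cholesterol synthesis and uptake were lower in 18 of 25 cases and higher in 1, with a median of -0.43, and 19 changed when adjusted over the list alone. The sterol enzymes SQLE (77.6 ± 3.69 to 46.0 ± 0.909 CPM), CYP51A1 (120.2 ± 5.47 to 78.9 ± 1.95 CPM) and MSMO1 (89.4 ± 6.20 to 43.9 ± 1.79 CPM, in a run) fell. TM7SF2, a sterol reductase gene named after its value was seen, rose by 0.83 ± 0.12. In fatty acid synthesis 9 of 15 fell and 4 rose, and 13 changed when adjusted over the list alone. The desaturase SCD fell from 785 ± 50.9 to 272.5 ± 12.1 CPM and the citrate lyase ACLY from 475 ± 14.04 to 276 ± 3.71 CPM, and the elongases ELOVL1 (-1.08 ± 0.07) and ELOVL5 (-0.91 ± 0.07), both in runs, fell as well. Camera gave an adjusted p of 0.00023 for cholesterol synthesis and 0.038 for fatty acid synthesis, and an adjusted p of 0.69 for both with an estimated correlation. The fatty acid synthesis call was also lost without the genes of the runs (0.066), without replicate 1 (0.054), replicate 2 (0.079) or replicate 3 (0.056) of the group labelled KO, with limma-voom (0.086), on ranks (0.16) and with the neighbour offset (0.094).

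Antigen presentation genes of MHC class I were lower in 11 of 13 cases, with a median of -0.58, and all 13 changed when adjusted over the list alone. HLA-B fell from 222 ± 26.6 to 126 ± 2.55 CPM, HLA-C from 236 ± 14.6 to 159 ± 5.05 CPM and the peptide transporter TAP1 from 30.8 ± 3.49 to 16.7 ± 0.853 CPM. The HLA genes are near-identical to each other and highly variable, so their counts are uncertain. B2M (0.25 ± 0.08) and PSMB10 (0.37 ± 0.11), named after their values were seen, rose, and both calls were lost without WT replicate 1, WT replicate 3, or replicate 2 or replicate 3 of the group labelled KO, and that of B2M also with the neighbour offset. None of these genes lay in a run. Camera gave an adjusted p of 0.0065, against an adjusted p of 0.74 with an estimated correlation and 0.074 with the neighbour offset. Interferon-stimulated genes held 18 lower and 5 higher of 34, with 25 changed when adjusted over the list alone, and no difference from other genes was detected (camera, adjusted p = 0.083), although the list passed in TPM (0.040). With an estimated correlation its adjusted p was 0.74 (camera). IFIT5 (-1.34 ± 0.12) and IFI44 (-0.87 ± 0.07), both in runs, ISG15 (20.2 ± 1.71 to 10.1 ± 0.397 CPM) and HERC5 (-0.66 ± 0.06, in a run) were lower.

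NF-kB targets rose in 13 of 25 cases, fell in 6 and did not pass in 6, with 20 changed when adjusted over the list alone, and camera gave an adjusted p of 0.065, which passed without WT replicate 1 (0.0498) and with the neighbour offset (0.022). With an estimated correlation the adjusted p was 0.74 (camera). The chemokine CCL2 rose from 0.705 ± 0.143 to 4.17 ± 0.111 CPM, CX3CL1 from 14.6 ± 0.463 to 29.6 ± 0.803 CPM, the apoptosis inhibitor BIRC3 from 124 ± 20.2 to 266 ± 22.9 CPM and TNFAIP2 from 523 ± 11.6 to 865 ± 14.2 CPM. Of 15 TAX1BP1 and A20 partners, 6 rose and 3 fell, and 9 changed when adjusted over the list alone. TNFAIP3, which encodes A20, rose from 36.6 ± 3.02 to 55.3 ± 1.11 CPM, the kinase IKBKE from 20.2 ± 0.417 to 36.4 ± 2.93 CPM, TBKBP1 from 10.7 ± 0.501 to 18.9 ± 0.337 CPM and TRAF2 from 49.95 ± 2.33 to 65.0 ± 3.70 CPM. No difference of the partner list from other genes was detected (camera, adjusted p = 0.26).

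Kidney and epithelial genes moved apart within their lists. Of 15 tested proximal tubule genes 8 rose and 2 fell, with PDZK1 (0.82 ± 0.08) and PAX8 (0.46 ± 0.06) higher and the cadherin CDH6 lower, from 150 ± 10.7 to 35.6 ± 0.938 CPM. Of 17 tubular injury markers 6 rose and 9 fell. The lipocalin LCN2 rose from 41.0 ± 3.38 to 258 ± 24.9 CPM and the integrin ITGB8 from 3.64 ± 0.749 to 31.9 ± 4.22 CPM, while SOX9 fell from 19.0 ± 1.78 to 5.99 ± 0.123 CPM and CD44 from 196.5 ± 8.28 to 108.4 ± 2.46 CPM. Among 29 epithelial junction and keratin genes, 7 rose and 11 fell, and 21 changed when adjusted over the list alone. KRT19 fell from 7.32 ± 0.904 to 0.225 ± 0.0655 CPM, CLDN4 from 16.4 ± 1.82 to 3.17 ± 0.458 CPM and CLDN2, in a run, from 24.4 ± 0.663 to 1.39 ± 0.416 CPM, and the desmocollin DSC2 rose from 12.6 ± 0.561 to 37.6 ± 0.666 CPM. Of 32 mesenchymal and matrix genes 7 rose and 16 fell, with TGFB2 falling from 9.27 ± 0.276 to 0.228 ± 0.222 CPM, COL8A1 from 13.5 ± 1.07 to 1.64 ± 0.287 CPM and COL6A1 from 55.0 ± 0.611 to 27.6 ± 0.710 CPM, and COL12A1 rising from 74.7 ± 7.42 to 184 ± 4.21 CPM. In the tubule, injury and matrix lists as many genes passed when adjusted over the list alone, and no difference of these 4 lists from other genes was detected (camera, adjusted p = 0.42, 0.87, 0.37 and 0.071). The matrix list passed without the low-count filter (0.044), without the genes of the runs (0.012) and with the neighbour offset (0.0044), against an adjusted p of 0.69 with an estimated correlation (camera).

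Few markers of other cell types were tested. Of the podocyte and parietal cell markers 5 were tested, 4 rose and 1 fell, and all 5 changed when adjusted over the list alone. SYNPO (0.91 ± 0.06), PODXL (0.71 ± 0.06), CRB2 (2.13 ± 0.31) and PAX8, which the proximal tubule list also holds, were higher, and CLDN1, named after its value was seen, was lower (-0.27 ± 0.06). Camera gave an adjusted p of 0.027, against an adjusted p of 0.69 with an estimated correlation, and the call was lost in DESeq2 (0.055), limma-voom (0.055) and on ranks (0.085). The distal nephron, fibroblast, endothelial and leukocyte lists had 2 tested members each and no set test. SCNN1A (4.20 ± 0.288 to 12.8 ± 0.648 CPM) and AVPR2 (0.239 ± 0.154 to 0.863 ± 0.218 CPM) of the distal nephron rose. COL1A1 of the fibroblast list (0.28 ± 0.09), ESAM of the endothelial list (0.61 ± 0.16) and CD74 of the leukocyte list (0.51 ± 0.07) rose, and CD68 (-0.75 ± 0.11) fell. The call of COL1A1 was lost without WT replicate 1, WT replicate 3 or replicate 3 of the group labelled KO and with the neighbour offset.

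**Figure D2:**
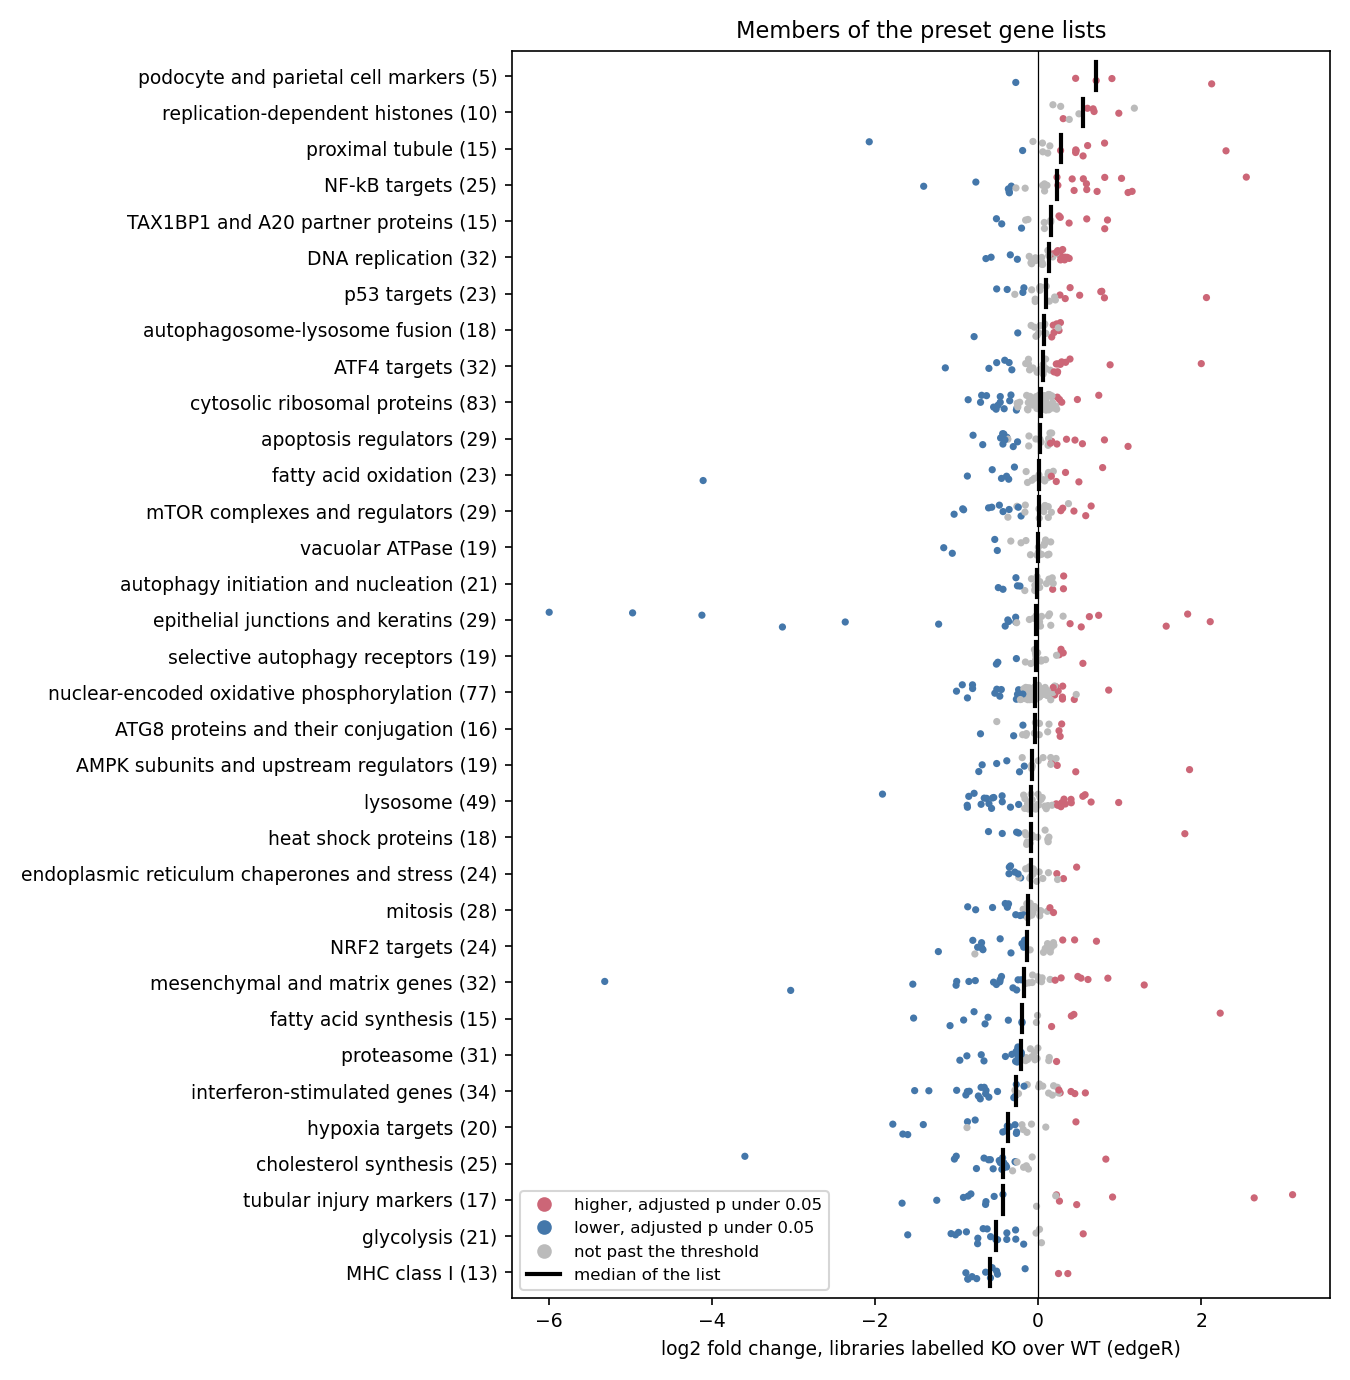
Log2 fold changes (horizontal axis, libraries labelled KO over WT, edgeR) of the tested members of the 34 gene lists with at least 5 tested members, ordered by their median; points are genes, coloured by direction where the adjusted p was under 0.05, black bars are list medians, and the number of tested members follows each name. The MHC class I (-0.58) and glycolysis (-0.52) lists had the lowest medians and the podocyte and parietal cell list (0.71) the highest.

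Changed genes were not spread evenly along the chromosomes. The search along the order of 11193 placed genes found 13 runs of neighbouring genes, all of them lower in the libraries labelled KO, with 1185 genes (10.6%) and a median log2 fold change of -0.57, against 0.03 for genes outside. The longest run, from PUDP to STAG2, held 273 genes, of which 91.2% had a fold change below 0, with a median of -0.58. The runs from AHDC1 to KIF2C (154 genes) and from SCNN1D to TMEM51 (101 genes) had medians of -0.80 and -0.79. The shuffled gene orders gave 0 runs in any of 200 repeats. With the genes of lower expression between their ends the runs held 1359 tested genes, and these held 1044 of the 3315 genes with a known position called lower (31.5%). Without these 1359 genes 5074 of 11498 genes changed, and 13 members of the AMPK and autophagy initiation lists did.

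**Figure D3:**
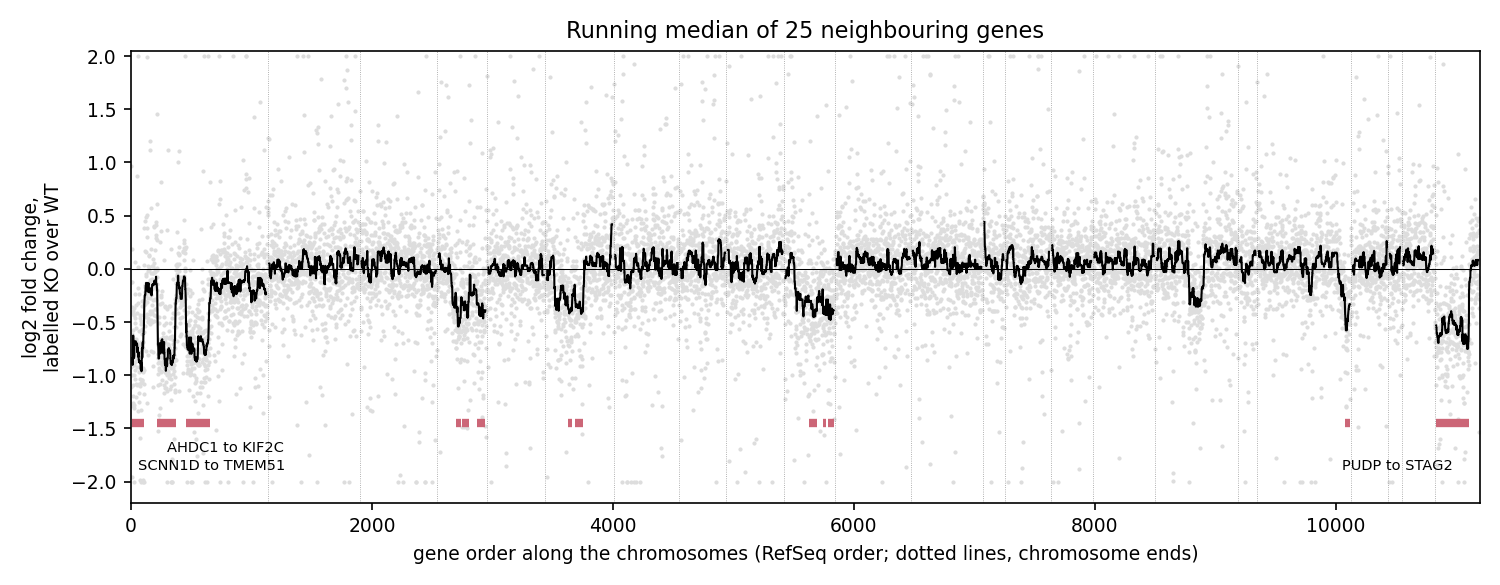
Log2 fold change (vertical axis, libraries labelled KO over WT, points limited to 2 in size) of 11193 genes in their order along the chromosomes (horizontal axis, RefSeq order); grey points are genes, the black line is the running median of 25 genes, dotted lines are chromosome ends and red bars are the 13 runs. The running median falls below -0.3 in every run, and the names are the end genes of 3 of the runs.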

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

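The alternatives without the genes of the runs and with the neighbour offset were chosen after seeing the data. The checks of genes cover 182 genes, which are the genes of the naming rule and those named after their values were seen, without TAX1BP1. Over 16 settings, 2855 checks kept direction and side of the threshold in 2782 cases, lost the call in 56 and turned direction in 17. TAX1BP1 is counted apart and turned direction in 3 settings. Most of the 182 genes were picked for a small adjusted p or a large change, so these shares do not describe all calls. Among the 6343 genes called in the main fit, 4580 were called with the neighbour offset, whatever their direction there. In DESeq2 5509 of them were called, and with other size factors 6318. The 34 lists kept their side of the threshold in 592 of 645 checks, lost a call in 17 and gained 1 in 36. Their direction was compared only where the list passed in the main fit or in the alternative, and 0 turned there. A list that passed in neither was counted as kept whatever its direction. With the neighbour offset the log2 fold change turned to 0.089 for TAX1BP1, -0.033 for PRKAA1, 0.34 for SESN2, 0.019 for FUNDC1, 0.035 for PPT1, 0.37 for MTOR, 0.011 for ATP6AP2, 0.073 for GCLM, 0.27 for PGD, 0.39 for ACADM, 0.069 for CDCA8, 0.32 for CLSPN, 0.17 for RPL5 and 0.061 for SARS1, which follows from subtracting the median of their neighbours. Of these, SESN2, MTOR, PGD, ACADM and CLSPN passed in the opposite direction. Their p-values leave out the error of the offset, so they do not settle the direction of these genes. TAX1BP1 turned to 0.044 in TPM and 0.012 without WT replicate 3, ULK1 to 0.013 with total counts only, 0.057 in TPM and 0.013 without WT replicate 2, and PRKAA1 to -0.043 without WT replicate 2. None of these 3 genes passed in any of these settings, and the cause was not tested. In TPM 571 genes changed at least 2-fold, and the cause was not tested, since the unit, scaling, filter, pseudocount and test all differ. Of the gene lists 0 were called with an estimated correlation and 23 by fry, which asks another question.

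Leaving out 1 library at a time gave 5161 to 7237 changed genes (2350 to 3432 higher, 2811 to 3805 lower), 1181 to 1202 at least 2-fold, 14 to 19 AMPK and autophagy initiation genes, 5 to 8 lists, 4143 to 6390 genes in TPM and -0.095 to 0.012 for TAX1BP1, -0.043 to 0.12 for PRKAA1 and -0.0416 to 0.013 for gene ULK1. DESeq2 called 5662 genes, the replicate block 6161 and the neighbour offset 5501. The replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated across genes at 0.0053, 0.050 and -0.12. The median, mean or test of a list differed in sign for the vacuolar ATPase (median 0.0037, mean -0.18), mTOR (0.011, -0.12), AMPK (-0.07, 0.011), selective receptors (-0.03, 0.0063), tubular injury (-0.43, 0.0054), apoptosis (0.02, -0.02), fatty acid oxidation (0.011, -0.20) and ribosomal (0.03, -0.03) lists. In TPM the podocyte list had too few members for a test, and 9 named genes were under the filter. Genes with few counts in a group have wide counting intervals.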

Other observations

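Stress and degradation genes not described so far held members of both directions in the libraries labelled KO. Of 31 proteasome genes 18 fell and 1 rose, with a median log2 fold change of -0.21, and 20 changed when adjusted over the list alone. PSMD3 (163.7 ± 3.50 to 103.4 ± 2.26 CPM, mean ± SD, n = 3), PSMB3 (-0.70 ± 0.09 SE), and PSMB2 (-0.96 ± 0.09) and PSMA5 (-0.87 ± 0.08), both in runs of lower neighbours, fell. Camera gave the proteasome list an adjusted p of 0.065, which passed in DESeq2 (0.0058), limma-voom (0.0039), on ranks (0.0032), in TPM (0.0082), without the low-count filter (0.028), without WT replicate 1 (0.0498) or WT replicate 3 (0.011), without the genes of the runs (0.023) and with the neighbour offset (0.019). With an estimated correlation the adjusted p of the proteasome list was 0.98 (camera). Of 24 NRF2 targets 3 rose and 11 fell, with GCLM (-0.80 ± 0.08) and PGD (-0.69 ± 0.07), both in runs, and AKR1C3 (-1.22 ± 0.14) lower and ABCC3 (0.72 ± 0.06) higher. Of 32 ATF4 targets 11 rose and 6 fell, with NUPR1 (5.43 ± 0.465 to 21.7 ± 1.22 CPM) and ATF5 (0.88 ± 0.07) higher and CTH (-1.14 ± 0.08) and SARS1 (-0.60 ± 0.06), both in runs, lower. Of 24 endoplasmic reticulum stress genes 3 rose and 6 fell, with SEL1L (0.47 ± 0.07) higher and HSPA5 (-0.34 ± 0.06), EDEM1 (-0.36 ± 0.06) and PDIA3 (-0.24 ± 0.05) lower. Of 18 heat shock genes 1 rose and 4 fell, with CRYAB (6.03 ± 0.616 to 21 ± 1.72 CPM) higher and HSP90AA1 (-0.26 ± 0.05), HSP90AB1 (-0.44 ± 0.06, in a run) and BAG3 (-0.61 ± 0.08, in a run) lower. In these last 4 lists 14, 17, 9 and 5 genes changed when adjusted over the list alone, and camera gave an adjusted p of 0.56, 0.56, 0.80 and 0.98. With the neighbour offset the calls of PSMB2, PSMA5 and HSP90AB1 were lost, GCLM (0.073) and SARS1 (0.061) turned sign without passing, and PGD turned to 0.27 and passed as higher (adjusted p = 0.011, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

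Lists of growth and energy genes held members of both directions, except the histones, of which 0 fell. Of 23 p53 targets 8 rose and 4 fell, with BTG2 (2.21 ± 0.539 to 9.26 ± 1.16 CPM), FDXR (0.78 ± 0.08) and DDB2 (0.77 ± 0.09) higher. Of 29 apoptosis regulators 8 rose and 10 fell, with BBC3 (0.81 ± 0.10) higher and MCL1 (-0.43 ± 0.06) lower. Of 28 mitosis genes 2 rose and 10 fell, with CDC20 (-0.86 ± 0.07), CDCA8 (-0.77 ± 0.07) and KIF2C (-0.38 ± 0.06), all in runs, and CCNA2 (-0.40 ± 0.05) lower. Of 32 DNA replication genes 12 rose and 4 fell, with MCM5 (0.38 ± 0.06) higher and CDC6 (-0.34 ± 0.05), and CLSPN (-0.64 ± 0.08) and POLA1 (-0.58 ± 0.06), both in runs, lower. Of 23 fatty acid oxidation genes 5 rose and 7 fell. CPT1A, which brings fatty acids into mitochondria, fell from 21.7 ± 1.28 to 1.25 ± 0.141 CPM, ACADM (-0.36 ± 0.06, in a run) fell, and CPT1B (0.79 ± 0.11) and ECI1 (0.50 ± 0.07) rose. Of 77 nuclear genes of oxidative phosphorylation 9 rose and 13 fell, with NDUFS5 (145 ± 19.5 to 72.4 ± 1.94 CPM), ATP5IF1 (-0.93 ± 0.08), ATP5PB (-0.80 ± 0.07) and COX7B (-0.80 ± 0.10), all in runs, lower. Of 83 ribosomal protein genes 5 rose and 14 fell, with RPL22 (-0.86 ± 0.08), RPL5 (-0.69 ± 0.07), RPS4X (-0.71 ± 0.08) and RPL7L1 (-0.46 ± 0.05), all in runs, lower, and many of these genes have pseudogenes that share their reads. Of 10 replication-dependent histone genes 5 rose and 0 fell, with H2BC5 (0.69 ± 0.13), H2AC6 (0.68 ± 0.14), H2BC21 (0.99 ± 0.22) and H2BC4 (0.61 ± 0.15) higher, and these genes are near-identical to each other. In these 8 lists 12, 19, 10, 16, 12, 22, 16 and 6 genes changed when adjusted over the list alone, and camera gave an adjusted p of 0.21, 0.98, 0.26, 0.44, 0.56, 0.79, 0.98 and 0.16. The p53 targets passed with the neighbour offset (0.044), and the histones passed there (0.044), in limma-voom (0.040) and on ranks (0.013). With an estimated correlation the adjusted p was 0.69 for both lists (camera). With the neighbour offset the calls of CDC20, KIF2C, CDC6, POLA1, NDUFS5, ATP5IF1, ATP5PB, COX7B, RPL22, RPS4X and RPL7L1 were lost, and CDCA8 (0.069) and RPL5 (0.17) turned sign without passing. ACADM (0.39) and CLSPN (0.32) turned sign and passed as higher there (adjusted p = 0.00025 and 0.0080, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call of H2BC4 was lost in TPM.

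The main fit and the alternatives quoted below were fixed beforehand, apart from the neighbour offset and the fit without the genes of the runs. The tests of explanations, the splits and the gene families below were chosen after the results were seen. For the copy number test alone, the expected outcome was written before its result. That copy number test replaced an earlier version, which had been run on the genes that defined the runs and therefore decided nothing.

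TAX1BP1 messenger RNA stood at the WT level in the libraries labelled KO. A single mislabelled library is argued against, since 6 of 6 libraries correlated most with a library of their own group. A halving hidden by the spread is argued against as well, since the 95% interval of the KO over WT ratio had a lower bound of 0.881. An allele that keeps the messenger RNA while disrupting the protein may account for the ratio of 0.97, and it cannot be told apart from an unedited gene because a gene total holds no reads across an edited site. A wrong label on the whole group was not tested.

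The runs of neighbouring genes that were lower together may reflect a difference in DNA copy number between the cell populations. Genes of low expression, which had not been used to find the runs, had a median log2 fold change lower inside the runs than outside by a difference of -0.558 (174 against 1470 genes, 95% interval -0.698 to -0.387). The permutation p was 0.0001, the smallest that 10000 permutations can give. Both this p and the interval treat the genes as independent. The 174 genes lie among the neighbours of only 13 runs that shift together, so the certainty is overstated. Any cause acting on a whole stretch of genes would lower them too, so the difference does not single out copy number. GC content and gene length are argued against, since a correction for both moved the median of the longest run from -0.576 to -0.595. The corrected medians of the 13 runs lay between -0.83 and -0.34. Their bootstrap 95% interval lay below 0 in 13 runs and below -0.3 in 8. The runs had been chosen for low medians of these same genes, and the bootstrap treats the genes as independent. The intervals therefore add nothing to the argument. A coordinated response of the cells tied to the genotype that the labels give was not tested and stays open, and no DNA was measured.

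Of the genes with at least 1 CPM in WT, 26 had 3 counts or fewer over the libraries labelled KO, 12 of them with 0, against 3 genes in the other direction (TLR4, UNC80 and ADCYAP1, the last pair named after their values were seen). The smallest count expected in the libraries labelled KO from the WT level was 56.8. The choice of genes with at least 1 CPM in WT ensured such a value, so it is no test of too few reads. It shows only that these libraries were deep enough to count the genes at their WT level. A complete deletion that spans adjacent tested genes is argued against, since 3.85% of these genes had an adjacent tested gene at least 16-fold lower. A deletion of a single gene, or one that reaches only genes not tested, would not be seen this way. Of the 26 genes 6 lay in runs, beside 1359 of all 12857 tested genes. Descent of the libraries labelled KO from 1 or a few cells may account for the 26 genes, but it cannot be told apart from an effect of the genotype that the labels give because the design holds 1 cell population per group.

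The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 6343 genes, 1139 genes at least 2-fold and 18 AMPK and autophagy initiation genes, and the highest other split called 0 of each, so that 1 of 10 splits reached each of these counts. In TPM the real split called 5490 genes and the highest other split called 1. For gene lists 7 of 10 splits called at least the 6 lists of the real split, 5 of them called more, and the highest called 10. Every other split puts libraries of both groups on each side. The difference between the groups then adds to the spread within a side, so few gene calls could be reached there. Part of that difference also remains between the sides in the list tests. The other splits therefore do not measure chance for either kind of count.

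Gene families defined by the stem of the symbol were tested after the data had been seen, 208 in all. Camera gave an adjusted p of 8.1e-05 for the claudins CLDN (6 of 10 lower, 0 higher), 0.0023 for HOXA (6 of 9 lower, 1 higher), 0.0024 for ADAMTS (7 of 11 higher, 1 lower) and 0.0499 for HOXB (7 of 9 higher, 1 lower). With an estimated correlation the adjusted p was 0.999 for each of these 4 families (camera). HOXA7 (log2 fold change -4.05 ± 0.31), HOXA9 (-2.14 ± 0.07) and HOXA10 (-2.22 ± 0.09), which fell, are neighbours of TAX1BP1, and so are JAZF1 (0.99 ± 0.15), CREB5 (0.46 ± 0.08), SCRN1 (0.35 ± 0.05) and FKBP14 (0.22 ± 0.08), which rose, and HOXA11 (-0.70 ± 0.24) and PLEKHA8 (-0.34 ± 0.07), which fell, all named after their values were seen. The call of FKBP14 was lost in DESeq2, in TPM, with other size factors, without the low-count filter, with the replicate block, without the genes of the runs and without WT replicate 1 (0.22), WT replicate 2 (0.15), or replicate 1 (0.19) or replicate 2 (0.20) of the group labelled KO. The call of HOXA11 was lost in DESeq2 (log2 fold change -0.70), in TPM (-0.36), with the neighbour offset (-0.58) and without WT replicate 1 (-0.56), or replicate 1 (-0.73) or replicate 3 (-0.51) of the group labelled KO, and that of PLEKHA8 in TPM. The 10 neighbours of TAX1BP1 had a median log2 fold change of -0.10. The 10 neighbours of MYSM1 had a median log2 fold change of -0.0093.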
